A study of Mus musculus with 6 samples.

How the data were processed

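Poly(A) RNA of sorted neurons was sequenced after papain dissociation, total RNA isolation with a mirVana kit and stranded TruSeq library preparation, per the labels' protocols. The submitters' processing notes name FastQC, cutadapt, STAR, HTSeq and DESeq2, and the builds mm10 and GRCm38; their versions, settings and order are not given in the sources used here. The authors deposited 1 table with 23337 gene symbols, which holds a normalized signal for each of 6 libraries and their DESeq2 test. In it the authors give a mean over the 6 libraries, a log2 fold change of Sox6- over Sox6+, its standard error, a score (the test statistic) and a p-value with its adjusted p-value. The deposited signal is a read count divided by a size factor per library: 100.0% of values above 0 in each library were whole multiples of that library's step, within 0.01 of a whole number. The step, the value of 1 read, ran from 0.9241 to 1.1387, and that of Sox6- library 825 was 1.0071. For this library the step is too near 1 for an automatic check to tell normalized from raw values, and its reads were recovered in the same way as the others. The 6 libraries held from 10397924 to 12952768 recovered reads and between 13429 and 15043 genes with a read. Of the symbols, 6009 were at 0 in all 6 libraries.

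Groups were taken from the sample titles: 3 libraries of neurons expressing Sox6 and 3 of neurons not expressing it. Genes with a mean of at least 10 over the 6 libraries were tested (13175 genes), without reference to group. The values are not raw counts, so the main test was limma with trend and robust moderation on log2(value + 1), 2-sided, with no block and Benjamini-Hochberg adjustment at 0.05. A fold change or log2 difference is on that log2(value + 1) scale. It understates the change of genes low in every library of a group. A 0 in a single library of a group can instead enlarge the difference or turn its sign. Vip, at 0 in Sox6+ libraries 825 and 1211, had a log2 difference of -4.49. Its mean was nevertheless higher in Sox6+ neurons, at 3585.4 against 1162.8. Of tested genes, 1244 had a 0 in some Sox6+ library and 542 in some Sox6- library. The test, the filter, the gene lists and the alternatives were fixed before the data were examined. The rule for genes to name took Sox6, the 10 largest differences in each direction among genes past the threshold with non-overlapping groups and a mean of at least 50, without predicted genes, Rik clones and pseudogenes, and the list members of smallest p. The other 20 genes past the threshold, and genes named for their value in single libraries, were chosen after their values were seen, as were Slc17a6, Calb1, Anxa1, Lpl, Th, Slc6a3, Npy, Crh, Igf1, Sema3a, Kcnq5, Gad1 and Tyrobp among the list members. Some genes that the rule names, or that passed the threshold, are not reported here.

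There were 15 gene lists and 10 lists of cell type markers, of which 21 had at least 3 tested members. Each was tested with camera on the moderated statistics of the same fit with a preset correlation of 0.01, with camera with an estimated correlation, and with fry, adjusted over the 21 lists. Camera's own refit of the model had been used at first, and was replaced by the form fixed beforehand after both sets of values had been seen; the same 10 lists were called, in the same directions. No list call held with an estimated correlation; fry, which tests whether the genes of a list move 1 way on balance, called 5 lists. Versions were R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Gene positions come from GENCODE M21 on GRCm38, matched by symbol, with 20961 symbols found.

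Replicates were compared before averaging. Pearson correlations of log2 values ran from 0.796 to 0.92 within groups and from 0.754 to 0.92 between groups, and chi-square per gene was at least 34.8 for all pairs, so no library was a copy of another. The first principal component, with 50.8% of the variance, set Sox6+ library 825 apart from the other 5. Alternatives were the library number as a block, pseudocounts of 0.5 and 8, other filters, TMM and quantile normalization, limma without trend or robust moderation, edgeR and DESeq2 on the recovered reads, edgeR with the block, library weights, and leaving out each library or each number. Taking Sox6 out of the ventral-tier list, and genes shared between the neuropeptide, dorsal-tier and GABAergic lists out of each, was chosen after the data were seen.

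The fit was tested on simulated counts for the comparison of Sox6+ with Sox6- neurons, with 13175 genes, 5 runs and 200 changed genes per run. Limma recovered 18.5% of genes changed 2-fold, 70.6% of those changed 4-fold and 96.1% of those changed 16-fold, with 11.4 false calls per run. EdgeR recovered 15.9%, 69.1% and 94.5%, with 9.8 false calls per run.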

Results

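RNA was sequenced from dopaminergic neurons of the substantia nigra pars compacta (SNc), the midbrain nucleus whose neurons project to the dorsal striatum. The neurons came from adult C57BL/6 mice carrying Sox6-FSF-Cre, Th-2A-Flpo and the RC-Frepe reporter, an intersectional design in which 2 recombinases decide which fluorescent protein a cell makes. After papain dissociation, neurons that express Sox6 were sorted by their GFP (Sox6+), and neurons that do not were sorted by mCherry (Sox6-). Each group had 3 libraries, numbered 103, 825 and 1211 in both groups. The Sox6+ libraries held 11660282, 10397924 and 12952768 reads in genes for numbers 103, 825 and 1211, and the Sox6- libraries held 11674328, 11262784 and 11841366. Values are normalized read counts per library, given as mean ± SD. The labels do not say that the libraries came from separate animals, so the p-values measure the spread between these samples. The question was how the transcriptomes of the Sox6+ and Sox6- dopaminergic neurons of the SNc differ.

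Sox6, the transcription factor that defines the sort, lay at 563.6 ± 242.5 (SD, n = 3) in Sox6+ neurons and at 52.6 ± 45.1 (SD, n = 3) in Sox6- neurons. The gene lies on chromosome 7 from 115470872 to 116038796 on the minus strand (GRCm38). The 3 Sox6+ libraries held 840.5, 461.2 and 389.0 and the 3 Sox6- libraries held 103.6, 18.1 and 36.2, in the order 103, 825 and 1211, so the groups did not overlap. The log2 difference was 3.66 with a standard error of 0.597, and its adjusted p of 0.0528 (limma, Benjamini-Hochberg over all tested genes) lay just outside the threshold of 0.05. The exact two-sided permutation p was 0.1, the smallest that 3 libraries against 3 can give. In the authors' deposited table, Sox6 had an adjusted p of 1.07e-06. The call depended on the setting, and the adjusted p ran from 2.21e-06 with DESeq2 on the recovered reads to 0.702 without number 1211. Transcripts of the reporter proteins were not analysed here.

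Sox6+ and Sox6- neurons differed most in genes that Sox6+ neurons almost lacked. Somatostatin (Sst), an inhibitory neuropeptide, lay at 4312.2 ± 1359.9 (SD, n = 3) in Sox6- neurons and had 2 reads in the 3 Sox6+ libraries together. Ctxn3 and Ppp1r17, a protein phosphatase inhibitor, had 5 and 3 reads in Sox6+ neurons against 1659 and 917 in Sox6- neurons. Among genes higher in Sox6+ neurons, Cadm2, a synaptic cell adhesion molecule, was 3.22-fold higher and Sv2c, a synaptic vesicle protein, was 4.17-fold higher. In all, 17 genes were higher and 23 were lower in Sox6+ neurons among 13175 tested.

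Among genes past the threshold, the 10 largest increases in Sox6+ neurons began with Derl3, a component of endoplasmic reticulum-associated degradation, at 236.1 ± 14.2 against 34.3 ± 19.6 (SD, n = 3 each). Ldoc1 and Msi2, the latter an RNA-binding protein, had log2 differences of 2.38 and 2.13, with standard errors of 0.291 and 0.256. Gfpt2, an enzyme of the hexosamine pathway, and Sv2c followed at 2.11 and 2.06. Col25a1, a transmembrane collagen, lay at 1749.6 ± 493.9 against 485.5 ± 124.2, and Pou3f2, a POU-domain transcription factor, at 991.3 ± 268.5 against 278.7 ± 63.8. Cadm2 lay at 4063.9 ± 768.5 against 1247.6 ± 87.6. Homer2, a postsynaptic scaffold protein, and Serpine2, a secreted protease inhibitor, were 3.09-fold and 2.85-fold higher. The adjusted p of these 10 genes ran from 0.0172 to 0.0486 (limma).

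The read ratio of Sox6- over Sox6+ libraries was 6810 for Sst, with an exact 95% binomial interval of 1890 to 56300. It was 334 for Ctxn3 (143 to 1030) and 308 for Ppp1r17 (105 to 1490). Tnnt2, a cardiac troponin gene, had no read in the Sox6+ libraries and 331 in the Sox6- libraries, so it was at least 111-fold lower, taking 3 reads over the group as the floor. These intervals and the floor cover counting error only. C1ql1, a secreted C1q-like synaptic protein, lay at 17.9 ± 18.1 in Sox6+ neurons against 497.1 ± 113.0 in Sox6- neurons (SD, n = 3 each). Ptprk, a receptor-type tyrosine phosphatase, lay at 7.95 ± 4.33 against 246.0 ± 76.9, and Unc13c, a presynaptic priming protein, at 29.0 ± 14.3 against 308.5 ± 33.7. The potassium channel gene Kcnh7, the long non-coding RNA Rmst and the insulin-like growth factor binding protein Igfbp4 had log2 differences of -3.45, -3.21 and -3.01.

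**Figure D1:**
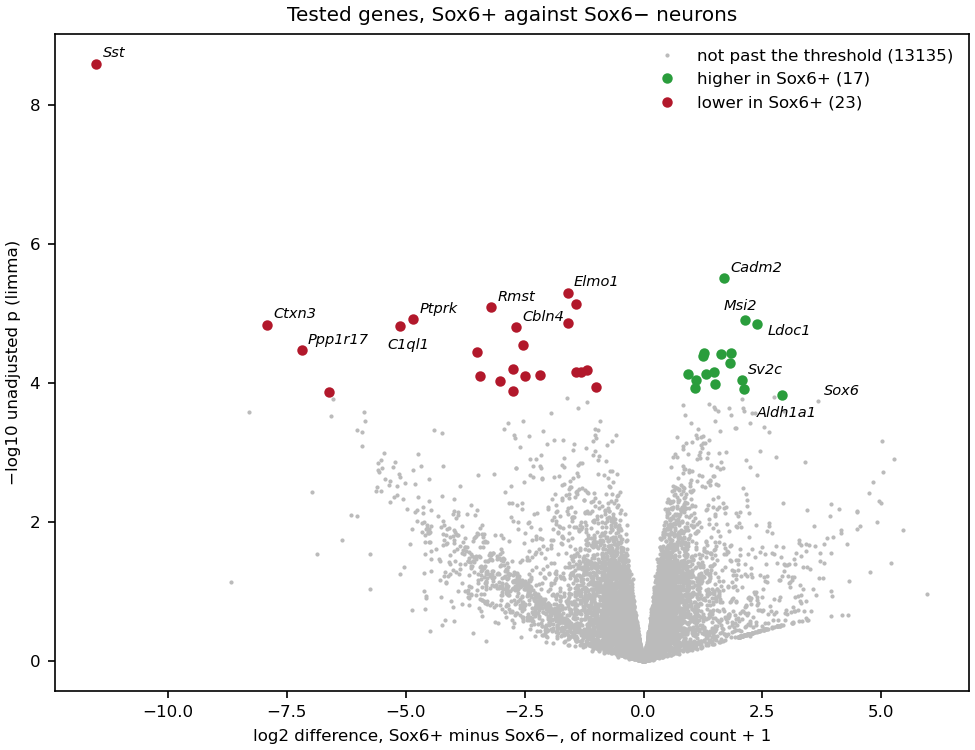
Each point is 1 of 13175 tested genes, with the log2 difference of Sox6+ minus Sox6- neurons on the x axis (log2 of normalized count + 1) and the negative log10 of the unadjusted limma p on the y axis. The 17 genes higher in Sox6+ neurons (green) and the 23 lower (red) passed an adjusted p of 0.05, with Sst farthest from 0 at a log2 difference of -11.50, and Sox6 and Aldh1a1 are named among the genes that did not pass.

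The other 20 genes past the threshold were 7 higher and 13 lower in Sox6+ neurons. The higher ones had log2 differences from 0.93 to 1.48 and included Dynlt3, a dynein light chain, at 8561.7 ± 510.3 against 4509.7 ± 591.6 (SD, n = 3 each), and Zdhhc2, a palmitoyltransferase. Tmem117, Mpp6, Rerg and Rbms3 were also among them. The lower ones had log2 differences from -1.0 to -2.75. Among them were Elmo1, a regulator of Rac signalling, at 977.8 ± 167.7 against 2930.2 ± 275.4, and Pcp4l1 at 489.2 ± 23.6 against 1304.2 ± 42.3. Avpr1a, the vasopressin V1a receptor, the calcium sensor Hpca, and Cbln4, a cerebellin-family synaptic organizer, were also lower, as were Ephb1, Fxyd6, Rcn1, Phlda3, Itm2a, C1qtnf4, Galntl1 and A230065H16Rik.

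All 40 genes had 3 Sox6+ values on one side of the 3 Sox6- values, as did 17.0% of all tested genes, where chance gives 10%. The authors' deposited table, made with DESeq2, held 411 genes at an adjusted p under 0.05, of which 181 were higher and 230 lower in Sox6+ neurons, and all 40 genes were among them with the same direction. The number of genes depended on the test, on the block and on single libraries. The edgeR quasi-likelihood test on the recovered reads called 6 genes, Cadm2 higher and Sst, Ptprk, Rmst, Elmo1 and Pcp4l1 lower, and DESeq2 on those reads called 387. With the library number as a block, limma called 134 genes higher and 133 lower, and edgeR called 63 and 57. Of the 40 genes, 1 passed without Sox6- library 1211, 9 without Sox6+ library 1211, 11 without Sox6- library 825, 16 without Sox6- library 103 and 21 without Sox6+ library 825. Without Sox6+ library 103, 39 of them passed, among 60 genes higher and 102 lower.

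The 6 genes that edgeR also called lie as follows in GRCm38. Cadm2 lies on chromosome 16 from 66655421 to 67620908 on the minus strand, and Sst on the same chromosome from 23889573 to 23890958, also on the minus strand. Ptprk spans 28074820 to 28597397 on the plus strand of chromosome 10, and Rmst 92071037 to 92165170 on its minus strand. Elmo1 spans 20090596 to 20608353 on the plus strand of chromosome 13, and Pcp4l1 171173262 to 171196268 on the minus strand of chromosome 1.

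Markers of ventral-tier SNc neurons were higher as a group in Sox6+ neurons, with a positive log2 difference in all 15 and a median of 2.24. Sox6 itself, which defines the sort, is among the 15, and without it all 14 were positive, the median was 2.14, 10 were higher over the list alone, and the list stayed past the threshold. The list differed from other genes in camera with the preset correlation (adjusted p = 2.69e-21), but not with an estimated one (adjusted p = 0.11 with an estimated correlation). Aldh1a1, the retinaldehyde dehydrogenase that marks the ventral tier, lay at 55670.9 ± 10544.0 in Sox6+ and at 12658.6 ± 6289.1 in Sox6- neurons (SD, n = 3 each). Satb1, a chromatin organizer, lay at 1323.4 ± 484.0 against 369.4 ± 88.4 and Kcns3, a potassium channel subunit, at 1314.6 ± 402.1 against 277.1 ± 150.7. Over all genes 0 passed with limma and 0 with edgeR, 9 were higher with DESeq2, and 11 had an unadjusted limma p under 0.05. Adjusted over the list alone, 11 were higher. Limma called 3 over all genes with the library number as a block, 2 without Sox6+ library 103, and 3 each without Sox6- library 103 or 825. The adjusted p over all genes was 0.0588 for Satb1, 0.0592 for Kcns3 and 0.0702 for Aldh1a1 (limma). The median difference between libraries of the same number was 2.12, 2.02 and 3.18 for 103, 825 and 1211, while GABAergic markers moved the opposite way (median -3.58, and -1.59 without Sst and Npy). Anxa1, a marker of part of the ventral tier, lay at 9102.3 ± 10388.1 against 1375.9 ± 1174.0.

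Markers of dorsal-tier and ventral tegmental area neurons were lower as a group in Sox6+ neurons, with a negative log2 difference in 12 of 13 and a median of -2.76. The neuropeptide list also holds 5 of these genes, Cck, Vip, Grp, Adcyap1 and Fst, and without them the list did not pass, with a median of -2.70 over 8 genes, 1 of them higher and 1 lower over the list alone. The camera adjusted p was 0.000722 with the preset correlation (adjusted p = 0.131 with an estimated correlation). Adcyap1, the gene of the neuropeptide PACAP, lay at 283.3 ± 180.4 in Sox6+ and at 1887.5 ± 754.7 in Sox6- neurons (SD, n = 3 each). Slc17a6, the vesicular glutamate transporter VGLUT2, lay at 600.0 ± 382.5 against 3182.7 ± 1419.8. Over all genes 0 passed with limma and 0 with edgeR, DESeq2 called 1 higher and 3 lower, and 5 had an unadjusted limma p under 0.05. Adjusted over the list alone, 4 were lower (Adcyap1, Grp, Fst and Slc17a6) and Tacr3, a neurokinin receptor, was higher at 1394.2 ± 353.9 against 613.9 ± 65.0. Calb1, the calcium buffer calbindin that marks the dorsal tier, lay at 12163.3 ± 2287.9 against 26206.0 ± 20777.4, with an adjusted p of 0.589 (limma). GABAergic markers moved the same way (median -3.58, and -1.59 without Sst and Npy). The median of the list was -1.14 with edgeR, -1.13 with DESeq2, -1.49 without Sox6+ library 825, and -1.26 and -1.53 without number 825 and 1211. Otx2, Neurod6 and Crhbp of this list were at 0 in Sox6+ library 825 and in no other library. Whether these 0s came from loss of transcripts in library 825 was not tested. Within the list alone, 7 were lower without Sox6+ library 825, 2 without Sox6- library 103 and 1 without Sox6- library 825, and over all genes limma called 1 higher and 1 lower with the block, 2 lower without Sox6+ library 103 and 1 lower without Sox6+ library 825. In Sox6+ library 825 Lpl, another marker of this list, lay at 1098.8, against 38.5 and 9.24 in Sox6+ libraries 103 and 1211. In the Sox6- libraries it lay at 558.3, 647.5 and 490.6. Sox6+ library 825 also held macrophage transcripts, such as Lyz2 at 26494.1. Which cells its Lpl came from was not tested.

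**Figure D2:**
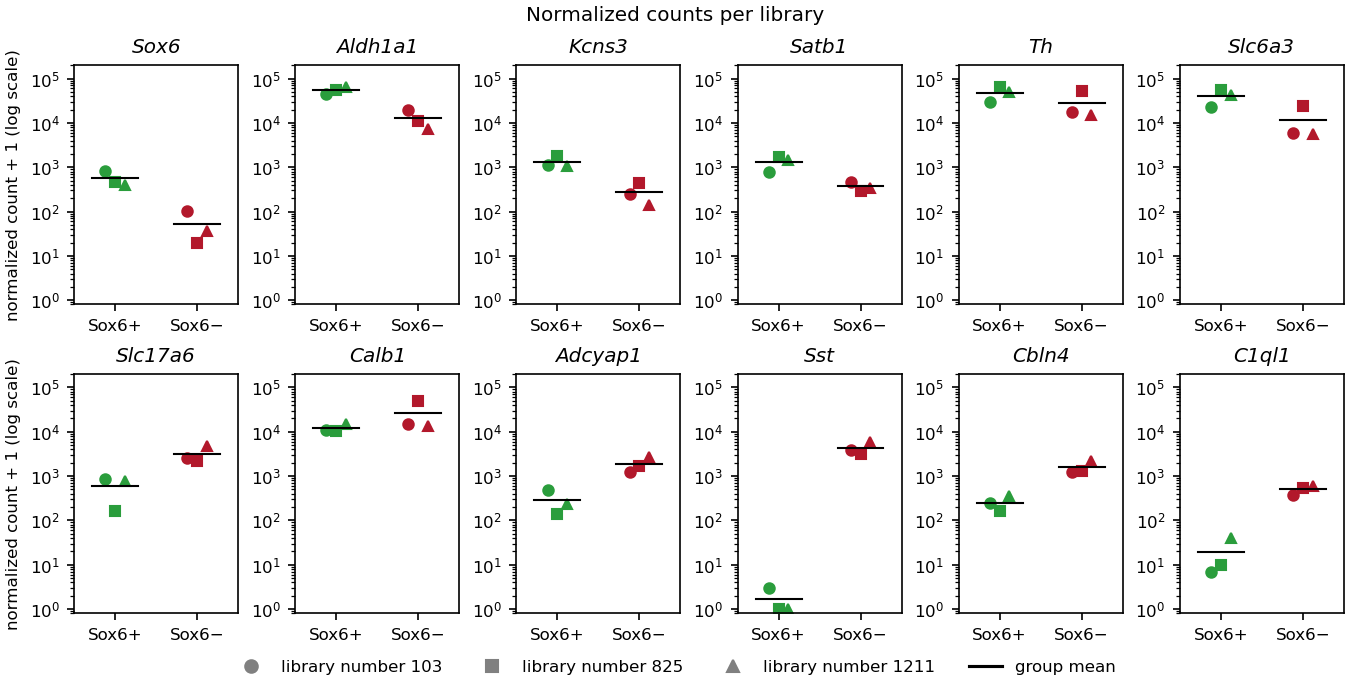
Normalized count + 1 of 12 genes on a log axis, for Sox6+ (green) and Sox6- libraries (red), with the marker shape giving the library number and the black line the group mean. Sox6, Aldh1a1, Kcns3 and Satb1 lie higher in all 3 Sox6+ libraries, Sst, Cbln4, C1ql1, Adcyap1 and Slc17a6 lie lower, and Th, Slc6a3 and Calb1 vary between Sox6- libraries.

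Genes of dopaminergic identity were higher as a group in Sox6+ neurons, with a positive log2 difference in 17 of 19 and a median of 1.16. With the preset correlation the camera adjusted p was 3.75e-07 (adjusted p = 0.417 with an estimated correlation), and fry did not call the list (adjusted p = 0.257). Th, the rate-limiting enzyme of dopamine synthesis, lay at 48004.3 ± 16789.7 in Sox6+ and 27945.9 ± 20385.2 in Sox6- neurons, and the dopamine transporter Slc6a3 at 40611.2 ± 16985.6 against 11857.3 ± 10414.0 (SD, n = 3 each). Over all genes 0 passed with limma and 0 with edgeR, 2 were higher with DESeq2, and 9 had an unadjusted limma p under 0.05. Adjusted over the list alone, the autoreceptor Drd2 and the vesicular monoamine transporter Slc18a2 were higher, at 698.3 ± 222.9 against 271.8 ± 127.0 and at 17801.1 ± 3756.4 against 6462.4 ± 3582.8. That count of 2 was 4 without Sox6+ library 103, 13 without Sox6- library 825 and 0 without any other single library. It was 8 with the block, and limma called 4 over all genes with the block and 4 without Sox6- library 825. Relative to the mean of the Sox6+ libraries, the median of the list was -1.68, -0.05 and -1.64 on the log2 scale in Sox6- libraries 103, 825 and 1211. Markers of GABAergic neurons moved the opposite way, at 3.53, 1.49 and 3.86 in the same libraries, against 2.43, -2.41 and 0.0 in Sox6+ libraries 103, 825 and 1211. Their log2 difference was negative in all 7, with a median of -3.58, which was -1.59 without Sst and Npy and -0.38 without Sox6+ library 825.

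Neuropeptide and secreted signal genes were lower as a group in Sox6+ neurons, with a negative log2 difference in 22 of 24 and a median of -2.77. The list stayed past the threshold without the 5 genes it shares with the dorsal-tier list (median -2.68), and without Sst and Npy, which it shares with the GABAergic list (median -2.68). The preset correlation gave a camera adjusted p of 2.69e-21 (adjusted p = 0.12 with an estimated correlation). Neurotensin (Nts) lay at 8.55 ± 14.8 in Sox6+ against 1114.9 ± 680.0 in Sox6- neurons (SD, n = 3 each). Sst and Cbln4 passed over all genes, and 12 were lower and 1, Igf1, higher when adjusted over the list alone. The 12 became 7 without Sox6- library 825, Igf1 did not pass with the block, with quantile normalization, with edgeR or without any 1 of the Sox6+ libraries, and over all genes 4 were lower with the block, 1 with edgeR, 7 with DESeq2, 7 without Sox6+ library 103 and 1 without Sox6- library 1211. Corticotropin-releasing hormone (Crh) had 4 reads in the Sox6+ libraries and 476 in the Sox6- libraries, a ratio of 120 with an interval of 46.5 to 441. Neuropeptide Y (Npy) had no read in the Sox6+ libraries, at least 79.9-fold lower by the same floor, and with Npy at that bound the median of the list was again -2.77. Relative to the mean of the Sox6+ libraries, the median of the list was 2.34, 2.12 and 3.34 on the log2 scale in Sox6- libraries 103, 825 and 1211, where that of the identity genes was -1.68, -0.05 and -1.64.

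Genes that mark GABAergic neurons were also lower in Sox6+ neurons as a group, with a negative log2 difference in all 7 tested and a median of -3.58. The call rests on Sst and Npy, which the neuropeptide list also holds: without them the list did not pass, with a median of -1.59 over 5 genes and 0 lower over the list alone. Their camera adjusted p was 1.3e-11 with the preset correlation (adjusted p = 0.368 with an estimated correlation), and fry did not call the list (adjusted p = 0.0513). Sst passed over all genes, and Sst and Npy were lower when adjusted over the list alone. Gad2 and Gad1, which make GABA, did not pass, with Gad2 at 624.1 ± 918.7 against 2582.7 ± 1677.9 and Gad1 at 2014.1 ± 2489.5 against 3597.4 ± 3664.9 (SD, n = 3 each). The values rest on single libraries: the median was -0.38 without Sox6+ library 825, where Gad1 and Gad2 were at 0, and -5.51 without Sox6+ library 103, where they lay at 4797.5 and 1679.1. It was -1.04 with edgeR and -1.03 with DESeq2, and adjusted over the list alone 1 gene was lower without Sox6- library 825 or 1211, and 1 was higher without Sox6+ library 825. Sox6+ library 825 also had the fewest genes with a read of any library, at 13429. Of 7979 genes high in Sox6- neurons, 7, 60 and 9 were at 3 reads or fewer in Sox6+ libraries 103, 825 and 1211. Whether the 0s of Gad1 and Gad2 came from loss of transcripts in library 825 was not tested.

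Axon guidance and cell adhesion genes were lower as a group in Sox6+ neurons, with a negative log2 difference in 34 of 52 and a median of -0.60. The camera adjusted p was 0.0358 (adjusted p = 0.209 with an estimated correlation). Ephb1, an ephrin receptor, passed over all genes, at 37.0 ± 0.86 against 281.2 ± 163.7 (SD, n = 3 each). Adjusted over the list alone, 5 were lower and 3 higher. The 3 higher were the cadherins Cdh11 and Cdh8 and the calsyntenin Clstn2, with Cdh11 at 1246.2 ± 379.4 against 430.8 ± 74.5 and Clstn2 at 1109.2 ± 306.4 against 320.6 ± 118.6. Sema3a, a secreted axon guidance cue, was among the lower, at 5.54 ± 9.6 against 90.5 ± 16.5. The GABAergic list moved the same way (median -3.58, and -1.59 without Sst and Npy). The call of the list was lost with edgeR, with DESeq2, with a mean of at least 50, and without Sox6- library 103 or 1211 (medians -0.69 and -0.57), and the median was -0.33 without Sox6+ library 825. Those 5 and 3 became 11 lower and 8 higher without Sox6+ library 103, with 8 lower without Sox6+ library 825, 3 without Sox6+ library 1211, 1 without Sox6- library 103 or 1211, and 10 lower and 8 higher with the block. Over all genes, 2 were higher and 3 lower without Sox6+ library 103, 1 higher and 3 lower with the block, 1 higher and 0 lower without Sox6- library 103, and 0 without any other single library or with edgeR.

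Of 31 potassium channel genes, 5 were higher and 3 lower when adjusted over the list alone. The 3 lower became 0 without any 1 of the Sox6- libraries and 7 without Sox6+ library 103, and the 5 higher became 3 without Sox6+ library 825 or 1211 or Sox6- library 103 or 1211. Among the higher were Kcns3, Kcnn3, the SK3 channel of dopaminergic neurons, at 371.4 ± 148.3 against 63.4 ± 42.8, and Kcnd3, an A-type channel, at 1859.3 ± 329.9 against 814.1 ± 267.6 (SD, n = 3 each). Kcnt1 and Kcnq5 were lower, at 94.1 ± 15.8 against 216.3 ± 30.6 and at 4.46 ± 3.87 against 65.1 ± 31.0. Over all genes 0 passed with limma and 0 with edgeR, DESeq2 called 4 higher and 2 lower, limma with the block 4 higher, and 10 had an unadjusted limma p under 0.05. Limma called 2 higher without Sox6+ library 103 and 1 higher without Sox6- library 825. The median and mean log2 differences were -0.06 and -0.38, opposite in sign to the camera test, which pointed upward (adjusted p = 0.757). Of 30 calcium, sodium and HCN channel genes 0 passed with limma in either adjustment, 0 with edgeR and 0 with DESeq2, and 4 had an unadjusted limma p under 0.05. With the block, limma called 1 higher and 1 lower over all genes and 1 higher and 3 lower over the list alone, edgeR called 1 higher, and without Sox6+ library 103 limma called 1 lower. Their median was -0.03 (camera adjusted p = 0.838), with Cacna1i at 12.7 ± 16.0 against 59.3 ± 34.8.

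Of 52 neurotransmitter receptor genes, 3 were higher and 4 lower when adjusted over the list alone. The cannabinoid receptor Cnr1 was lower, at 120.4 ± 89.2 against 851.0 ± 394.4, as were the glycine receptor subunit Glra2, at 134.5 ± 66.0 against 514.6 ± 155.2, and the GABA-A receptor subunit Gabrg3, at 25.5 ± 10.4 against 113.2 ± 19.2 (SD, n = 3 each). Tacr3 and Drd2 were among the higher. Limma and edgeR each called 0 over all genes, DESeq2 called 5 higher and 6 lower, and 21 had an unadjusted limma p under 0.05. The counts of 3 higher and 4 lower became 3 and 13 without Sox6+ library 103, 10 and 8 without Sox6- library 825, 1 and 4 without Sox6+ library 825 or 1211, and 0 and 0 without Sox6- library 1211. The block gave 9 higher and 17 lower, with 3 and 5 over all genes, where limma also called 1 higher and 2 lower without Sox6+ library 103 and 2 higher without Sox6- library 103. The median was -0.41 and the camera adjusted p 0.0964, but the list passed with the block, with edgeR and the block, and without Sox6+ library 103 (median -0.44). Among 23 genes of calcium buffering, Atp2a3, an endoplasmic reticulum calcium pump, lay at 161.3 ± 82.9 against 6.19 ± 5.8, and the sodium-calcium exchanger Slc8a1 at 1870.5 ± 340.1 against 1031.7 ± 326.0. These 2 were higher when adjusted over the list alone and with DESeq2, while 0 passed over all genes with limma and 0 with edgeR, and 5 had an unadjusted limma p under 0.05 (camera adjusted p = 0.617, median 0.16). The list alone gave 3 higher and 2 lower with the block (1 higher over all genes), 2 and 2 without Sox6+ library 103, 4 higher without Sox6+ library 825, 0 without Sox6+ library 1211, and 1 without Sox6- library 103 or 1211, and the list itself passed without Sox6+ library 825 (median 0.23).

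**Figure D3:**
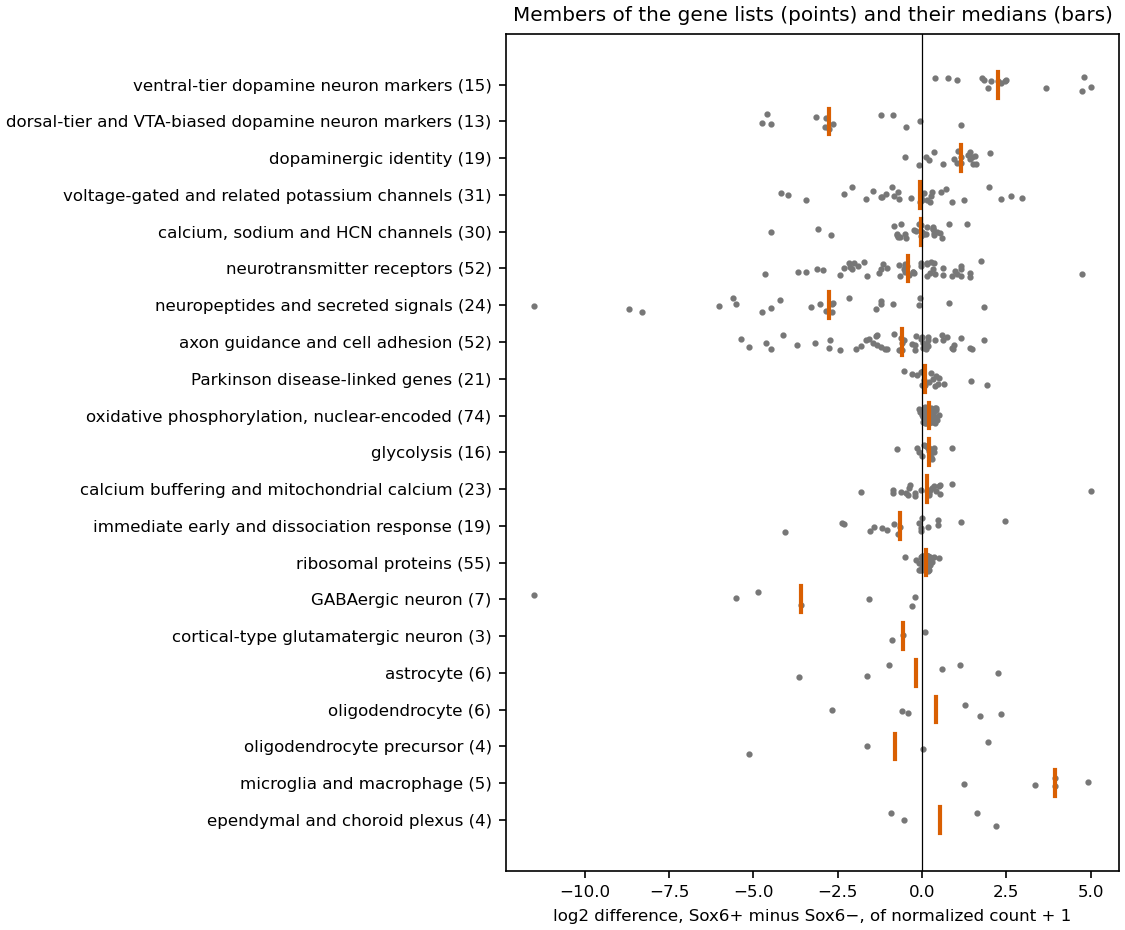
Log2 differences of Sox6+ minus Sox6- neurons (log2 of normalized count + 1) for the tested members of 21 gene lists, with a point for each gene, the list size in brackets and an orange bar at the median. The ventral-tier list lies at a median of 2.24, the dorsal-tier list at -2.76, the neuropeptide list at -2.77 and the oxidative phosphorylation list at 0.21.

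Nuclear-encoded oxidative phosphorylation genes were slightly higher as a group in Sox6+ neurons, with a positive log2 difference in 70 of 74 and a median of 0.21. With the preset correlation their camera adjusted p was 4.09e-10 (adjusted p = 0.368 with an estimated correlation), and fry did not call the list (adjusted p = 0.0711). In either adjustment 0 genes passed with limma, 0 passed with edgeR and 0 with DESeq2, and 14 had an unadjusted limma p under 0.05. Atp5g1, an ATP synthase subunit, lay at 5251.9 ± 878.3 against 3680.2 ± 382.1 and Ndufb2, a complex I subunit, at 5195.2 ± 431.6 against 3923.1 ± 339.5 (SD, n = 3 each). The median was 0.12 with quantile normalization, and the GABAergic list moved the opposite way (median -3.58, and -1.59 without Sst and Npy). Of 13 mitochondrially encoded genes, 0 were found by symbol among the genes the authors list, so this list could not be tested.

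Of 16 glycolysis genes, Ldhb, a lactate dehydrogenase subunit, was higher when adjusted over the list alone, at 21756.1 ± 2773.0 against 12070.6 ± 3293.9 (SD, n = 3 each), and Aldoc, an aldolase, lay at 2918.3 ± 177.9 against 5072.9 ± 1723.0. Markers of GABAergic neurons moved the opposite way (median -3.58, and -1.59 without Sst and Npy). The glycolysis list had a median of 0.21 and a camera adjusted p of 0.0255 (adjusted p = 0.459 with an estimated correlation). Over all genes 0 passed with limma and 0 with edgeR, DESeq2 called 1 higher and 1 lower, and 4 had an unadjusted limma p under 0.05. The call of the list was lost in 10 of 23 alternatives, edgeR, DESeq2 and quantile normalization among them, and without Sox6+ library 825 (median 0.12) or Sox6- library 103 (median 0.18). Within the list alone 0 were higher with edgeR or without any 1 library other than Sox6- library 103, without which 1 was higher and 1 lower, and the block gave 5 higher and 1 lower over the list alone and 1 and 1 over all genes. Ribosomal protein genes had a median of 0.11 over 55 genes and a camera adjusted p of 0.0395 (adjusted p = 0.876 with an estimated correlation), with a log2 difference of 0.52 for Rpl22 and Rpl15 at 2030.2 ± 404.9 against 1584.1 ± 311.3. No ribosomal gene passed in either adjustment, with 0 at an unadjusted limma p under 0.05, 0 with edgeR and 0 with DESeq2. That call was lost in 15 of 23 alternatives, TMM and quantile normalization among them, and the median was 0.03 without Sox6+ library 825, 0.07 without Sox6+ library 1211, 0.02 without Sox6- library 103 and 0.09 without Sox6- library 1211. It was 0.19 without Sox6+ library 103 and 0.20 without Sox6- library 825, where the call held.

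Of 21 genes linked to Parkinson disease 0 passed with limma in either adjustment, 0 with edgeR and 0 with DESeq2, and 1 had an unadjusted limma p under 0.05. Their median was 0.10 (camera adjusted p = 0.0964), the list passed without Sox6+ library 103 (median 0.16), and 1 gene was higher over the list alone with the block. Dnajc6, which encodes auxilin, lay at 1293.1 ± 141.1 in Sox6+ against 914.2 ± 104.4 in Sox6- neurons, and the ubiquitin hydrolase Uchl1 at 29291.4 ± 6840.0 against 22247.2 ± 7349.2 (SD, n = 3 each). Of 19 immediate early and dissociation response genes, Fos and Jund were lower when adjusted over the list alone. Fos lay at 125.1 ± 100.5 against 563.5 ± 240.2 and Jund at 1453.2 ± 228.8 against 2304.0 ± 356.5, with a median of -0.67 for the list (camera adjusted p = 0.112). None of these 19 passed over all genes with limma or edgeR (0 each), 2 were lower with DESeq2, and 3 had an unadjusted limma p under 0.05. Over the list alone 1 was lower without Sox6- library 825 and 0 without Sox6+ library 1211 or Sox6- library 103 or 1211, and over all genes 1 was lower with the block and 1 without Sox6+ library 103. The list passed with library weights, without the filter on low values, with a mean of at least 50, and without Sox6+ library 825 (median -0.60) or number 825, and its median was -0.26 without Sox6+ library 1211.

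Transcripts of macrophages were high in 1 Sox6+ library, and the microglia and macrophage list was higher as a group in Sox6+ neurons, with a positive log2 difference in all 5 tested genes and a median of 3.93. The camera adjusted p was 1.76e-05 (adjusted p = 0.315 with an estimated correlation). In Sox6+ library 825, Lyz2, a lysozyme of myeloid cells, reached 26494.1 and Ctss, a cathepsin, 3543.6, while both lay at 13.4 or lower in the other 5 libraries. In this library 50 genes lay at 200 or above and over 20 times above the other 5 libraries, with 0.599% of its reads. With the 2 genes at 0 in all Sox6- libraries, Ctss and Tyrobp, at their floor, the median was 4.91. Without library 825 the median over the same 5 genes was 1.20, and 1 of them stayed above the filter on low values, so the list test had too few members. Over all genes 1 member was higher (limma). Adjusted over the list alone 3 were higher, Mrc1 and P2ry12 among them. Those 3 became 1 without Sox6+ library 103 or 825 or Sox6- library 103 or 1211, with 1 gene left to test without Sox6+ library 825. Over all genes 0 passed without Sox6+ library 825 or 1211 or Sox6- library 103 or 1211, 0 with edgeR, 2 with DESeq2 and 4 with edgeR and the block. The median was 6.76 with edgeR, 6.95 with DESeq2, 2.34 with a pseudocount of 8, 1.28 with library weights and 0.94 without the filter on low values.

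Markers of other brain cells did not differ as lists with all 6 libraries and no block. Camera gave an adjusted p of 0.757 for 6 astrocyte genes, 0.838 for 6 oligodendrocyte genes, 0.0964 for 4 oligodendrocyte precursor genes, 0.757 for 3 cortical-type glutamatergic genes and 0.757 for 4 ependymal and choroid plexus genes. Their medians were -0.19, 0.42, -0.80, -0.58 and 0.54, and the astrocyte median and mean (-0.38) were opposite in sign to its camera direction. The precursor list passed with the block, without Sox6+ library 1211 (median -0.57) and without number 1211. C1ql1 was the only member past the threshold over all genes, and the precursor list also held Vcan, higher when adjusted over the list alone at 114.6 ± 43.2 against 29.6 ± 13.4 (SD, n = 3 each). Vcan did not pass without Sox6+ library 1211, where 0 were higher, and over all genes 0 of the precursor list passed with edgeR or without Sox6+ library 825 or Sox6- library 825 or 1211. Without Sox6+ library 103, 2 of the precursor list were lower and 2 of the astrocyte list higher over the list alone. In the astrocyte list Slc1a3 had no read in the Sox6+ libraries and lay at 33.3 ± 38.7 in Sox6- neurons, and Slc1a2 lay at 672.9 ± 289.3 against 430.8 ± 143.5. In the oligodendrocyte list Mag lay at 17.6 ± 27.5 against 43.6 ± 26.2 and Ugt8a at 51.0 ± 27.4 against 18.0 ± 15.7. Tmem212 and Ccdc153 of the ependymal list lay at 61.6 ± 106.7 against 0.34 ± 0.58 and at 53.6 ± 92.8 against 1.55 ± 2.68, with nearly all of it in Sox6+ library 1211. Cux2 of the cortical list lay at 17.7 ± 15.9 against 27.4 ± 8.55. Of the serotonergic and noradrenergic list only Tph2 was tested, at 33.7 ± 19.2 against 19.1 ± 16.8, and no endothelial or erythrocyte gene reached the filter on low values.

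**Figure D4:**
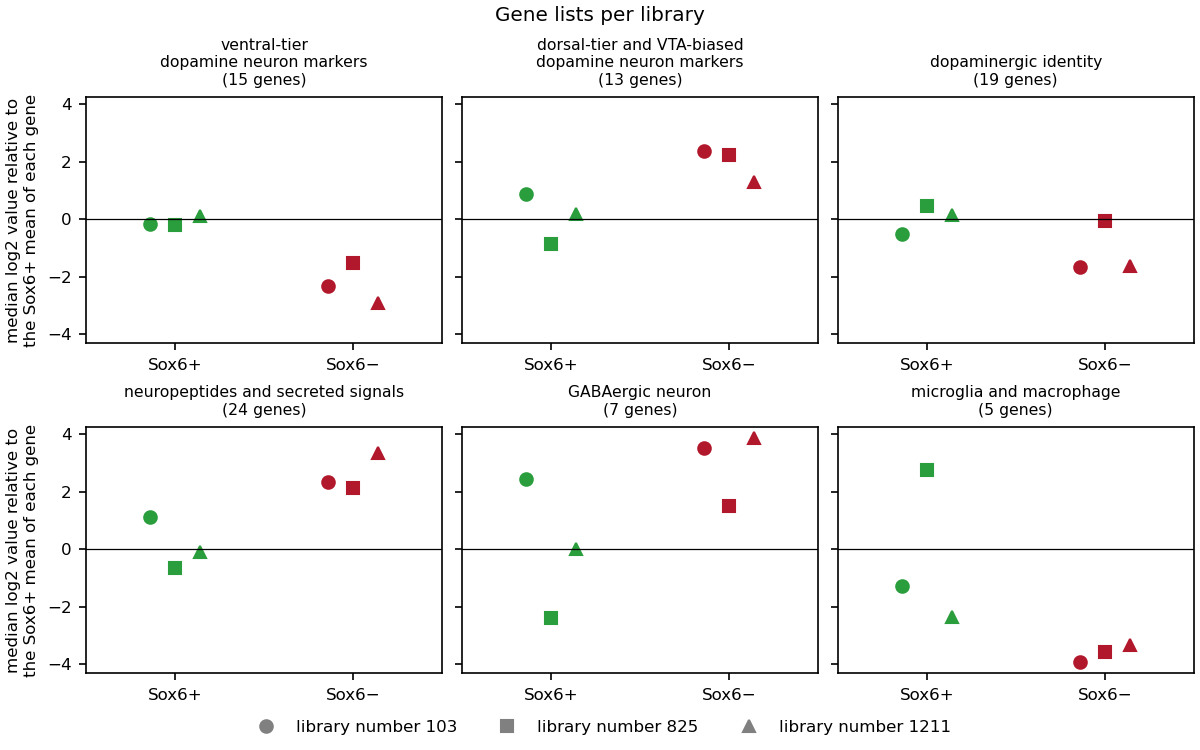
Median log2 value of 6 gene lists in each library, relative to the mean of the 3 Sox6+ libraries for each gene, with Sox6+ libraries in green, Sox6- libraries in red and the shape giving the library number. The dopaminergic identity list lies at -1.68, -0.05 and -1.64 in Sox6- libraries 103, 825 and 1211, and the microglia and macrophage list at 2.75 in Sox6+ library 825.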

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

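All alternatives in this paragraph were planned. The 17 genes higher and 23 lower in Sox6+ neurons became 134 and 133 with the library number as a replicate block, 34 and 35 with a pseudocount of 8, 7 and 14 without the filter on low values, 95 and 111 with library weights, and 4 and 20 without trend or robust moderation, which kept 5 of the 40 genes. On the recovered reads they were 1 and 5 with edgeR, 171 and 216 with DESeq2, and 63 and 57 with edgeR and the block; the cause was not tested. Leaving out libraries or numbers gave from 0 to 60 higher and from 1 to 102 lower. The lowest came without Sox6- library 1211 or without number 1211, each with 1 gene, and the highest without Sox6+ library 103. The share of higher genes among those called was 42.5%; it ran from 16.7% with edgeR to 52.5% with edgeR and the block over the alternatives with all libraries, and from 0% to 77.3% over the libraries left out. Same-number correlations of deviations from the group means were 0.268, 0.172 and 0.079 for 103, 825 and 1211; the last is under 0.1, so the numbers were not taken as pairs, although every library correlated best with its own number, a hint from the data. The log2 difference of Sox6 was 3.66 with the block, 3.42 with a pseudocount of 8 and 3.66 with a mean of at least 50. It was 3.78 with quantile normalization, 3.42 with DESeq2, 3.62 with edgeR and the block and 3.56 with library weights. All of these were past the threshold. Sox6 did not pass with a pseudocount of 0.5 (limma adjusted p = 0.0596), without the filter on low values (0.0641) or with TMM (0.0563). Nor did it pass without trend or robust moderation (limma adjusted p = 0.216) or with edgeR (edgeR adjusted p = 0.158). Over the libraries or numbers left out its log2 difference ran from 3.1 to 4.32, with limma adjusted p from 0.0153 to 0.702. Of the 20 genes named by rule, none changed sign; 20 stayed past the threshold with DESeq2, 4 with edgeR and 1 without Sox6- library 1211. The count of lists called was 10; it was 0 with an estimated correlation and 5 with fry, from 7 to 12 over the libraries left out, and from 7 to 12 under the other alternatives. With a mean of at least 50, 17 of the 21 lists had enough members to test, and 20 did without Sox6+ library 825 or without any 1 number.

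Some genes and lists not past the threshold changed direction. The log2 difference was 1.62 for Vip with edgeR and 1.62 with DESeq2. For Ttr it was 0.36 with a pseudocount of 8, 2.85 with edgeR, 2.86 with DESeq2, 1.39 with edgeR and the block, and 3.21 with library weights, for Siglec5 -0.13 with library weights, and for Car4 0.1 with a pseudocount of 8, 0.83 with edgeR, 0.86 with DESeq2 and 0.54 with edgeR and the block. Over the libraries left out it ran from -4.09 to 2.04 for Ttr, from -5.94 to 0.17 for Gad1, from -0.22 to 2.23 for Mbp, from -3.15 to 2.62 for Car4 and from -0.1 to 2.55 for Cd9. The direction of the list test turned for potassium channels with fry (median -0.06), calcium, sodium and HCN channels with a mean of at least 50 (-0.02), cortical-type genes with library weights (-0.10) and astrocyte genes without the filter (-0.41). It also turned for some libraries left out, where the medians ran from -0.3 to 0.04 for potassium channels, -0.17 to 0.0 for calcium, sodium and HCN channels, -0.12 to 0.23 for calcium buffering, -1.75 to 0.88 for cortical-type, -0.16 to 1.02 for oligodendrocyte and -2.78 to 2.04 for ependymal genes. The cause was not tested. After the data were seen, members were taken out of 4 lists. The dorsal-tier and GABAergic lists were then no longer called without the genes shared with the neuropeptide list (medians -2.70 and -1.59). The ventral-tier list without Sox6 (2.14) and the neuropeptide list without either set of shared genes (-2.68 each) were. In the simulation limma recovered 18.5% of 2-fold changes among genes with a mean of at least 50.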

Other observations

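Tests of explanations were chosen after the values they explain had been seen, except the count of other splits and the alveolar macrophage markers, which were unseen although the idea came from genes already seen. Genes named here were chosen after their values were seen. Single libraries held high values of peptide and epithelial genes. Rln3, the gene of the neuropeptide relaxin-3, reached 26850.2 in Sox6- library 1211 and lay at 2.96 or lower in the other 5. Vip reached 10756.1 in Sox6+ library 103 and was at 0 in both other Sox6+ libraries, with 557.4, 75.5 and 2855.6 in Sox6- libraries 103, 825 and 1211. Ttr, a marker of the choroid plexus, lay at 4849.7 in Sox6+ library 1211 and at 642.7 in Sox6- library 1211, against 14.4 or lower in the other 4, and the ciliary genes Ccdc153 and Tmem212 reached 160.8 and 184.8 in that Sox6+ library. Mbp, a myelin gene, lay at 1943.8 in Sox6+ library 825 and at 139.1 or lower elsewhere. Tlr3, a sensor of double-stranded RNA, lay at 27.6, 59.2 and 17.6 in Sox6+ libraries 103, 825 and 1211 and was at 0 in all 3 Sox6- libraries, and Samd9l, an interferon-induced gene, lay at 10.9, 124.1 and 73.9 against at most 2.78. Neither passed the threshold over all genes, with adjusted p of 0.216 and 0.211 (limma). In the authors' deposited table both passed, with adjusted p of 0.001 and 0.0013 (DESeq2).

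The real split of the 6 libraries gave 40 genes and the highest of the other splits 1, so 1 of the 10 splits gave as many genes, and 10 splits are too few for a share under 0.05. With edgeR the real split gave 6 and the highest other split 1.

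Sst and Ppp1r17 were at 3 reads or fewer in all 3 Sox6+ libraries and at 100 or more in all 3 Sox6- libraries, the only 2 of 7979 such genes. Random loss of transcripts from the Sox6+ libraries would give 5.9e-05 such genes, with a limit of 0. That number takes the losses as independent in each library and equally likely for all genes. The rule was set after the values of Sst and Ppp1r17 had been seen, so the count of 2 had to exceed the limit and decides nothing. In the mirror direction 0 of 7608 genes met the rule. Loss of transcripts, a difference between the 2 populations and cells of another kind in the Sox6- sort all stay open for Sst and Ppp1r17. The gate on mCherry, in mice with Th-2A-Flpo, is meant to remove cells of another kind, and how well it did so was not tested.

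Macrophage transcripts in Sox6+ library 825 may come from myeloid cells that passed the sort, which a GFP gate should remove. The high values had been seen in that library, so a fall without it was bound to follow and does not test the source. Without that library the median of the microglia and macrophage list went from 3.93 to 1.20. Whether the list itself stayed past the threshold could not be tested there, with 1 of 5 members above the filter. C1qa, C1qb and C1qc together reached 0.064% of Ctss in that library, which argues against microglia, and of 11 markers of alveolar macrophages, 6 (Ear2, Fabp4, Cidec, Itgax, Krt79 and F7) stood at least 20 times above the other libraries, while Cd9, Car4, Il18, Pparg and Siglec5, which other libraries also held, did not, and the levels of Chi3l3 (7505.2), Ccl6 (5939.4), Ear1 (444.1) and Marco (277.8) were known when the idea was formed, and of 6 lung epithelial genes none stood apart, with Sftpc at 11.4 (4.8 in another library), Scgb1a1 at 13.7 and Sftpb, Sftpa1, Sftpd and Ager at 0; macrophages of alveolar type are a candidate source whose route into the library is open.

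The higher neuropeptide genes in Sox6- neurons may come from non-dopaminergic cells that dilute that sort. The gate on mCherry, in mice with Th-2A-Flpo, is meant to remove such cells, and how well it did so was not tested. Identity genes were least reduced in Sox6- library 825, and dilution would then put the neuropeptide list there lower than in the other 2 libraries, by a log2 ratio of -4.33. The median was -0.33, with an interquartile range of -1.43 to 0.24, between that value and 0. Of the Sox6- libraries, 825 was also lowest for the GABAergic list, at 1.49 against 3.53 and 3.86, relative to the mean of the Sox6+ libraries. Sox6+ libraries 103, 825 and 1211 themselves lay at 2.43, -2.41 and 0.0 for that list, so Sox6+ library 103 lay above Sox6- library 825. The prediction rests on an identity deficit near 0 in library 825 (-0.05), while Sox6+ libraries themselves ran from -0.53 to 0.44, so it cannot be told apart from a difference between the 2 populations.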
